A study of Homo sapiens with 21 samples.

How the data were processed

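RNA-seq and MiGS were analysed from 21 samples of 11 cultures of colon fibroblasts, of which 10 cultures had both assays. Groups and replicate numbers came from the labels, which name normal, colitis and cancer patients. The groups, tests, gene lists, rule for named genes and most alternative settings were chosen before the data were examined. The planned test of MiGS windows was replaced once the files were seen.

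For RNA the deposited table held read counts per Ensembl gene and FPKM values for each library. The submitters' processing notes name STAR 2.4.0.1, featureCounts, edgeR and the build hg19 (GRCh37), without saying which tool made which file. The FPKM values the authors deposited equal the count times a constant divided by gene length and library total, with 1 length per gene in every library. They were used only for gene lengths. The strand setting of the counting is not given in the sources used here. Of 63677 gene IDs, 52181 had a name, and those held 99.4% of counts. The 36220 autosomal IDs, 1 per symbol, held 88.27% of counts, and mitochondrial genes held 8.12%. Genes of the sex chromosomes were left out of the tests, with those of X added in an alternative.

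For MiGS the deposited files held signal per 50 bp bin of the autosomes, which is read coverage times 1 factor per library. The submitters' processing notes name Bowtie2 and hg19. All values were whole multiples of the smallest value of their file within a tolerance of 0.001. Of the genome, 6164007 bins were listed in at least 1 library, and each reached a coverage of about 4 in at least 1 library. A weakly methylated region can therefore be missing. Coverage was summed in windows of 1000 bp and divided by 3.15 bins per read, the run length of isolated reads, to give read equivalents. Windows with a mean of at least 10 read equivalents were tested, which left 406901 of 968521. No unenriched input was used here, so levels are relative enrichment and not methylation levels.

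RNA counts were tested with edgeR's quasi-likelihood F-test on 15285 genes kept by its expression filter, with TMM scaling and all 10 libraries in 1 fit with 3 group means. The common biological coefficient of variation was 0.6. P-values were adjusted by Benjamini and Hochberg's method with a threshold of 0.05. The 22 gene lists were tested with limma's camera with a preset correlation of 0.01 on log2 CPM (prior count 2), adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The lists covered cell cycle, interferon response, inflammatory genes, glycolysis and hypoxia, and WNT, R-spondin and BMP niche signals. Another held immediate-early and stress genes, called immediate-early genes for short. Further lists held collagens, proteases, myofibroblast genes, TGF-beta targets, growth factors, HOX genes, regional transcription factors and DNA methylation writers. The rest were p53 and senescence genes, colorectal cancer promoter methylation markers and 6 sets of markers of other cell types.

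The planned MiGS test was edgeR on read counts. Since the files hold signal, log2 CPM of the read equivalents (prior count 2, TMM) was tested with limma (trend and robust moderation, 11 libraries in 1 fit), and edgeR on rounded read equivalents became an alternative. Called windows of the same direction closer than 3000 bp were merged into regions. The share of read equivalents in the strongest 5% of tested windows (20345 windows) and the mitochondrial share were compared with 2-sided exact permutation tests, 16 in all with library totals, adjusted together. The strongest windows were those with the highest mean share over the 11 libraries.

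Named genes were the 5 with the smallest p per direction in each comparison, since fewer than 5 passed, up to 4 members with the smallest p of each list, and 13 genes given in any case. Some genes that meet this rule are not reported here. Named windows were the 5 with the largest called change per direction and a mean of at least 20 read equivalents. For genes with at most 3 counts in each library of a group, counts are given in place of a fold.

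Libraries held 34184833 to 42611030 RNA counts and 12.3 M to 24.6 M MiGS read equivalents. On counts simulated for cancer against normal cultures over 15285 genes, the RNA test recovered 1 of 50 genes changed 2-fold, 16 of 50 changed 4-fold, 42 of 50 changed 16-fold and 44 of 50 changed 64-fold, with 0 false calls. On simulated values of 406901 windows, limma recovered 0 of 50 shifted by 0.5 on the log2 scale, 6 of 50 shifted by 1, 26 of 50 shifted by 2 and 50 of 50 shifted by 4, with 6 false calls. Genes and windows were simulated independently of each other, without differences between libraries that many of them share. The false calls therefore do not give the error rate in the real libraries, where other splits also call windows.

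Alternatives changed the scaling, the filter, the samples in the fit, the window size (500 bp), the test (DESeq2), the replicate block and each library in turn. Covariates, quantile normalization and edgeR on rounded read equivalents, the run nearest to the planned window test, were added after the data were seen. Linear models of culture values with 3 group means and a covariate, with 95% intervals and each library left out in turn, were also added then. So was a comparison of a chromosome 1 stretch with all stretches of 362 kb, in steps of 50000 bp, that held at least 148 tested windows. Promoter tests, promoter against expression and CpG density need a genome or annotation of hg19, which was not used here, and were left out. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.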

Results

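Fibroblasts, the connective tissue cells that make and remodel matrix, had been cultured from the colon of normal, colitis and cancer patients, and DNA and RNA came from the same cultures. Stranded paired-end RNA-seq covered 10 cultures, of which 4 were from cancer, 3 from colitis and 3 from normal patients. MiGS, in which methylated DNA fragments are captured with a methyl-CpG-binding domain and sequenced, covered 11 cultures, of which 4 were from cancer, 4 from colitis and 3 from normal patients. The 10 cultures with RNA all had MiGS as well. RNA libraries held between 34184833 and 42611030 counts, and the listed bins of the MiGS libraries held the equivalent of 12.3 M to 24.6 M reads. The comparisons ask how the transcriptome and the methylome differ among the 3 kinds of culture. Nothing in the labels says whether cultures of a group came from separate donors, so p-values measure the spread between these cultures.

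Gene expression placed the cancer cultures toward one end of the main axis of variation, with a normal culture among them. The first principal component of the RNA data held 33.8% of the variance, and the cancer cultures scored between -101 and -8.92 on it. The colitis cultures scored between 22.6 and 32.4. Normal replicates 2 and 3 scored 97.3 and 124, whereas normal replicate 1 scored -38.6. In MiGS the first component held 33% of the variance, with cancer cultures between -302 and -63.3 and the others between -37.9 and 346. The second MiGS component (13.2%) set normal replicate 2 apart at -364, with every other culture between -10.7 and 91. Cancer replicate 1 had a higher Spearman correlation of MiGS windows with each colitis culture (0.83 to 0.867) and normal replicate 1 (0.841) than with any other cancer culture (0.77 to 0.82). In RNA it was nearest to cancer replicate 2 (0.942). Cancer replicate 4 was nearer in RNA to each colitis culture (0.928 to 0.95) and normal replicate 1 (0.942) than to any other cancer culture (0.921 to 0.927).

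Cell-cycle genes were expressed at lower levels in cancer than in normal cultures. The mean of the 47 listed genes was 3.03 ± 0.97 log2 CPM (SD, n = 4) in cancer and 5.17 ± 0.79 (SD, n = 3) in normal cultures, and 46 of the 47 had a negative fold change, with a median log2 fold change of -2.24. MYBL2, a transcription factor of proliferating cells, was 9.31-fold lower (log2 fold change -3.22, SE 0.74, adjusted p = 0.188). The replication licensing genes MCM2 and CDT1 were 3.63-fold and 6.17-fold lower, and CENPA, the centromeric histone, was 5.64-fold lower. The list fell as a set by limma's camera with a preset correlation (adjusted p = 3.82e-18). It did not pass with an estimated correlation (adjusted p = 0.599). In edgeR no member passed over all genes tested, 38 of the 47 had an unadjusted p below 0.05, and 36 passed when adjusted over the list alone. The mitochondrial genes held 11.1 ± 5.53% of counts (SD, n = 4) in cancer and 6.07 ± 1.37% (SD, n = 3) in normal cultures (2-sided exact permutation p = 0.171, where the smallest possible p is 0.0571). With that share as a covariate the median of the cell-cycle list was -1.31 (adjusted p = 1.43e-11, and adjusted p = 0.648 with an estimated correlation).

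Interferon-response and inflammatory genes were expressed at higher levels in cancer than in normal cultures. All 45 interferon-response genes had a positive fold change, with a median of 1.70, and the list mean was 5.37 ± 1.05 log2 CPM (SD, n = 4) against 3.10 ± 0.85 (SD, n = 3). GBP4, a guanylate-binding protein, was 251-fold higher (log2 fold change 7.97, SE 1.60, adjusted p = 0.188), XAF1 6.78-fold and the antiviral gene RSAD2 189-fold. The chemokine CXCL10 had 9 to 264 counts per cancer library and 0 to 3 per normal library. Among 36 inflammatory cytokine and chemokine genes, 27 were higher, with a median of 1.94. Complement C3 was 347-fold higher (log2 fold change 8.44, SE 1.73), the acute-phase gene SAA1 71.9-fold and the NF-kappaB inhibitor NFKBIA 1.94-fold, and SAA2 had 8 to 103 counts per cancer library and 0 to 3 per normal library. Both lists rose as sets in camera (adjusted p = 1.39e-13 for interferon response and 4.16e-06 for inflammatory genes). With an estimated correlation neither passed (adjusted p = 0.599 for both). Adjusted over the list alone, 15 interferon and 12 inflammatory genes passed in edgeR, all higher, and none passed over all genes tested. SAA1 and SAA2 are near-identical in sequence, so their separate values are uncertain.

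**Figure D1:**
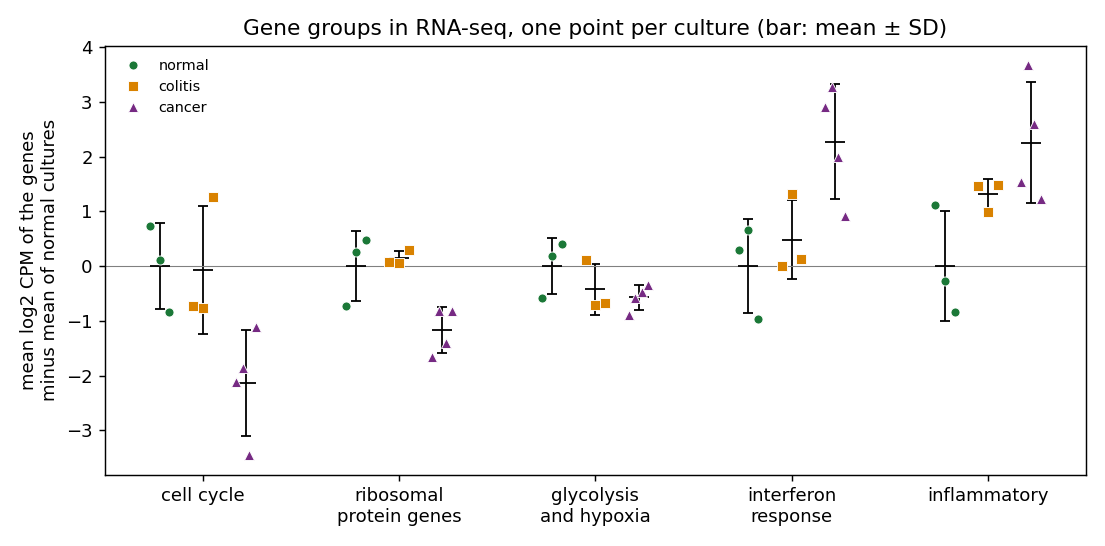
Mean log2 CPM of the genes of 5 groups in each culture (points), minus the mean of the normal cultures, with the group mean and SD as bars. Cell-cycle means lay between 1.72 and 4.05 log2 CPM in the 4 cancer cultures and between 4.32 and 5.90 in the 3 normal cultures, and all 79 ribosomal protein genes, a group chosen after the values were seen, had a negative cancer against normal fold change under TMM, RLE and upper-quartile scaling (78 with total counts).

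Single genes did not pass the threshold in this comparison. edgeR's quasi-likelihood test called 0 of 15285 genes at adjusted p 0.05 (smallest adjusted p = 0.103), with 1199 higher and 1545 lower genes at unadjusted p below 0.05, while DESeq2 called 492 higher and 481 lower. The values of 1981 genes (13%) did not overlap between the groups, against an average of 5.71% over random groupings. Genes vary together, so the share of any 1 grouping can lie far from that average, and its spread was not computed. The genes nearest the threshold were LYNX1, which encodes a modulator of nicotinic receptors and was 8.55-fold higher at 5.86 ± 0.37 against 2.68 ± 0.77 log2 CPM (SD, n = 4 and 3), and PAX8-AS1, which was 18.6-fold lower (log2 fold change -4.22, SE 0.51, adjusted p = 0.103). SLC22A15, the zinc and manganese transporter SLC39A8, MCTP2 and the scavenging chemokine receptor ACKR4 were 4.99-fold, 9.84-fold, 13.1-fold and 24.2-fold higher. BZW2 and the translational repressor EIF4EBP1 were 4.03-fold and 7.35-fold lower, and the pseudogenes C19orf48P and RPL3P4, whose reads can come from parent genes, 3.40-fold and 4.85-fold lower. The strand setting of the counting is not given in the sources used here, so PAX8-AS1 cannot be told from its sense partner. Without normal replicate 1, edgeR called 486 genes (222 higher and 264 lower), and without cancer replicate 4 or normal replicate 2 it called 1 each.

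**Figure D2:**
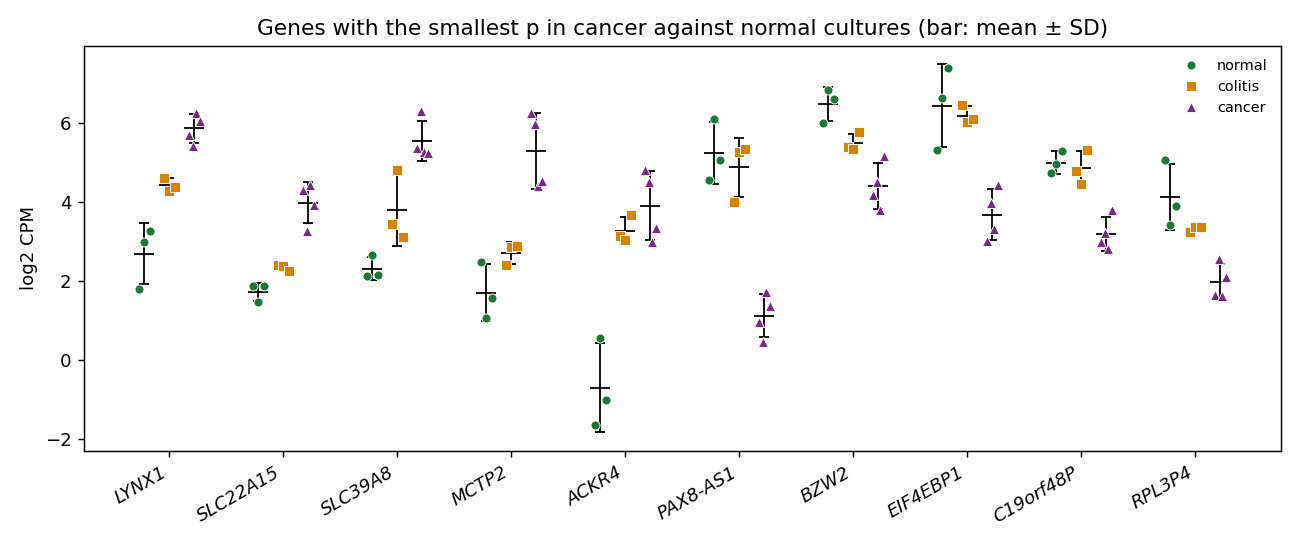
Expression (log2 CPM) in each culture of the 10 genes with the smallest p per direction in cancer against normal cultures, 5 higher and 5 lower, with group means and SD as bars. No gene passed adjusted p 0.05 in edgeR, and for each of the 10 the cancer and normal cultures did not overlap.

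Glycolysis genes and the list of immediate-early and stress genes were lower on average, and niche signal genes higher, in cancer than in normal cultures. The glycolysis mean of normal replicate 1 (6.63 log2 CPM) lay within the 6.32 to 6.87 of cancer cultures. Normal replicates 2 (7.40) and 3 (7.61) lay above that range. For immediate-early and stress genes the mean of normal replicate 1 (4.45) also lay within the cancer range (4.19 to 5.06). Of 34 glycolysis and hypoxia genes, 26 were lower (median log2 fold change -0.70), with TPI1 3.49-fold, LDHA 3.84-fold, BNIP3 3.82-fold and ENO1 2.35-fold lower. The list passed camera (adjusted p = 0.00301) but not with an estimated correlation (adjusted p = 0.66), and 5 of its genes passed as lower and 1 as higher when adjusted over the list alone. Of 45 genes on the list of WNT, R-spondin and BMP niche signals, 33 were higher (median 0.92). The list also holds antagonists, such as the BMP antagonist CHRDL2, so this count gives no direction of signalling. FRZB was 11.4-fold, RSPO2 24.5-fold and RSPO1 21.5-fold higher and the activin antagonist FST 6.68-fold lower (camera adjusted p = 0.00533, and adjusted p = 0.599 with an estimated correlation). Immediate-early and stress genes were lower (28 of 38, median -0.51, camera adjusted p = 0.0364, and adjusted p = 0.66 with an estimated correlation), with TRIB3 3.17-fold and MT1E 7.23-fold lower but EGR2 28.5-fold higher. This last call was lost without cancer replicate 1 (adjusted p = 0.193), cancer replicate 3 (0.091), normal replicate 2 (0.168) or normal replicate 3 (0.0814), with a stricter filter (0.0508), with upper-quartile factors (0.0516) and with the mitochondrial share (0.195) or the cell-cycle mean (0.388) as a covariate.

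The fibroblast programs on the fixed lists did not pass camera between cancer and normal cultures without a covariate. Collagen and matrix genes had a median log2 fold change of -0.41 (adjusted p = 0.531), with elastic-fiber gene FBLN5 4.40-fold higher and LOXL3 5.48-fold lower. Myofibroblast genes had a median of -0.30 (adjusted p = 0.743), with tenascin TNC 3.81-fold lower and PDGFRB 2.07-fold higher. TGF-beta targets had a median of 0.24 (adjusted p = 0.438), with ACVRL1 9.09-fold and COMP 39.5-fold higher. Growth factors and receptors had a median of -0.01 and a mean of 0.36 (adjusted p = 0.438), with IGFBP5 8.33-fold and FGF9 56.6-fold higher and IGF1 at 83 to 327 counts per cancer library and 1 to 3 per normal library. The median and mean of matrix-degrading proteases (-0.08 and -0.07, adjusted p = 0.743) and of regional transcription factors (-0.02 and -0.16, adjusted p = 0.585) were negative although camera ranked both lists up. MMP1 was 7.96-fold lower and CTSK 5.82-fold higher, and DLX1 and PAX8 were 49.9-fold and 14.7-fold lower. DNA methylation and chromatin writers (median -0.11, adjusted p = 0.282), p53 and senescence genes (0.16, 0.761), HOX genes (0.55, 0.761) and colorectal cancer promoter methylation markers (0.10, 0.745) did not pass either. Adjusted over the list alone, 2 TGF-beta genes, 1 growth factor gene and 1 p53 or senescence gene passed, all higher. With the cell-cycle mean as a covariate collagen genes (median -0.81, camera adjusted p = 0.0418) and myofibroblast genes (-0.67, 0.0378) passed as lower, but not with an estimated correlation (adjusted p = 0.645 and 0.509). Chromatin and DNA methylation writers passed camera as lower without normal replicate 2 (adjusted p = 0.0353), but not with all libraries and an estimated correlation (adjusted p = 0.837).

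Markers of other cell types did not pass camera between cancer and normal cultures without a covariate. Adjusted p was 0.569 for endothelial, 0.743 for mesothelial, 0.745 for smooth muscle and pericyte, 0.786 for leukocyte, 0.786 for epithelial and 0.951 for glial and neuronal markers. Smooth muscle and pericyte markers had a median log2 fold change of 0.29 and a mean of -0.47. With the cell-cycle mean as a covariate their median was -1.27 and the list passed as lower (camera adjusted p = 0.016), but not with an estimated correlation (adjusted p = 0.46). EPCAM had between 4 and 32 counts per library, PTPRC at most 1 and PECAM1 0 in all 10 libraries. VIM, the mesenchymal intermediate filament gene, had at least 88061 counts in each library and was 2.42-fold lower in cancer than in normal cultures (adjusted p = 0.205). ACTA2 (log2 fold change -1.23, SE 0.95), FAP (-0.81, SE 1.01) and COL1A1 (-0.98, SE 0.63) differed by less than 2 SE. The DNA methyltransferase genes DNMT1 (-0.66, SE 0.40), DNMT3A (0.45, SE 0.31) and DNMT3B (-0.45, SE 0.61) and the demethylase genes TET1 (-1.06, SE 0.74), TET2 (0.16, SE 0.46) and TET3 (0.04, SE 0.41) also did not pass (adjusted p between 0.4 and 0.97).

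MiGS windows were called in both directions between cancer and normal cultures. Chance is not excluded, since 3 of 35 splits of these cultures, the real one included, called at least 509 windows. Of 406901 windows of 1000 bp on the autosomes (hg19), 135 had higher and 374 lower signal at adjusted p 0.05 in limma, and 210 and 233 with total-read scaling. Named windows are the 5 per direction with the largest fitted change among called windows with a mean of at least 20 read equivalents. Where a group is near 0 reads, the fitted change and its order depend on the prior count of 2, so mean read equivalents per library are given. Those lower in cancer were on chromosome 19 from 36643001 to 36644000, with 1.7 read equivalents in cancer and 141.4 in normal cultures (log2 fold change -5.24, SE 0.40, adjusted p = 0.000149; -2.30 ± 0.30 against 2.94 ± 0.90 log2 CPM, SD, n = 4 and 3), and in the window before it from 36642001 (1.1 against 99.6). On chromosome 11 they were 0.4 against 59.1 from 1891001 to 1892000 and 2.9 against 128.5 from 1892001 to 1893000, and on chromosome 12 from 133159001 to 133160000 they were 14 against 303.4 (25.9-fold lower on the fitted scale). Those higher in cancer were on chromosome 6 from 34206001 to 34207000, with 48.1 read equivalents against 1.6 (log2 fold change 3.48, SE 0.46, adjusted p = 0.0106), and from 117085001 to 117086000 (47.3 against 3.9), on chromosome 12 from 127630001 to 127631000 (46.9 against 2.4), on chromosome 19 from 49936001 to 49937000 (145.5 against 13, 8.39-fold) and on chromosome 16 from 73087001 to 73088000 (41.5 against 4). Gene annotation of this build was not used here, so no window is assigned to a gene.

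The 374 lower windows formed 339 regions when windows closer than 3000 bp were merged, and the 135 higher windows 133 regions. The count depended on single libraries. It was 12421 (2847 higher, 9574 lower) without cancer replicate 1, 151 (14 and 137) without cancer replicate 2, 106 (8 and 98) without cancer replicate 3 and 84 (11 and 73) without cancer replicate 4. It was 3635 (2150 higher, 1485 lower) without normal replicate 1, 28045 (13027 and 15018) without normal replicate 2 and 85 (40 and 45) without normal replicate 3. With the share of reads in the top windows as a covariate, 3 windows were called, all lower, and DESeq2 called 90 higher and 12572 lower.

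**Figure D3:**
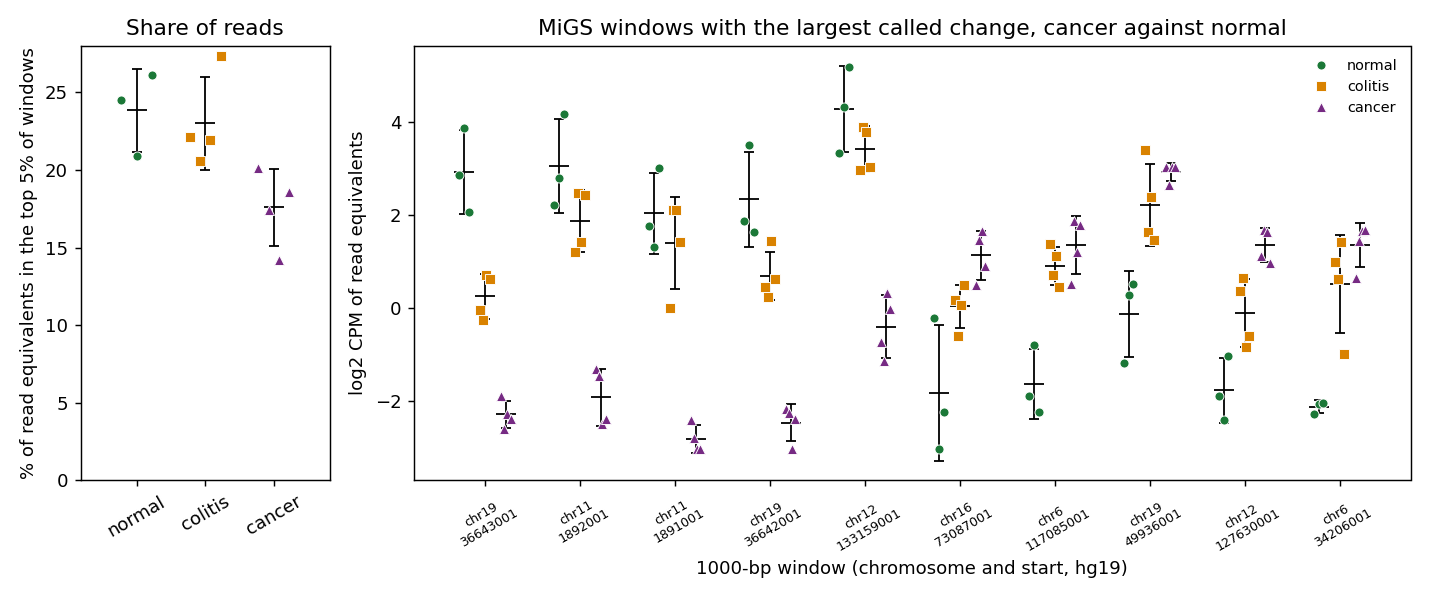
Left, percent of MiGS read equivalents that fall in the strongest 5% of windows, per culture; right, log2 CPM of the 10 windows with the largest fitted called change in cancer against normal cultures (5 per direction) and a mean of at least 20 read equivalents, with group means and SD as bars. The share was 14.2 to 20.1% in the 4 cancer cultures and 20.6 to 27.3% in the other 7, and in the window from 36643001 on chromosome 19 the cancer mean was -2.30 against 2.94 log2 CPM in normal cultures.

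The windows that were strongest on average over the 11 libraries held a smaller share of reads in cancer cultures. The share in each library's own strongest windows was not computed. A flatter enrichment can therefore not be told from a different set of strong windows. The strongest 5% of windows held 17.6 ± 2.5% of reads (SD, n = 4) in cancer, 23 ± 2.98% (SD, n = 4) in colitis and 23.8 ± 2.66% (SD, n = 3) in normal cultures. The difference of cancer from normal cultures had a 2-sided exact permutation p of 0.0571, the smallest this design allows, and that from colitis cultures 0.0286, likewise the smallest. Against all 7 other cultures together, a comparison added after the values were seen, it was 0.00606. None passed Benjamini-Hochberg adjustment over the 16 tests of library values (adjusted p = 0.305, 0.229 and 0.097). Windows were also ranked by their mean log2 CPM over the 11 libraries. The weakest 10% had a median log2 fold change of 0.57 in cancer against normal cultures and the strongest 10% one of -0.42.

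Windows lower in cancer cultures lay on all 22 autosomes, with 74 of the 374 on chromosome 1. Of these, 48 lay between 2992001 and 3354000, in a stretch of 296 tested windows whose median log2 fold change was -1.05. Mean signal over the stretch was 1.07 ± 0.26 log2 CPM (SD, n = 4) in cancer, 1.75 ± 0.15 (SD, n = 4) in colitis and 2.16 ± 0.30 (SD, n = 3) in normal cultures, and 95.3% of its windows were lower in cancer than in normal cultures. The windows within 1000000 bp on each side had a median of -0.26. The stretch was chosen after the values were seen.

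**Figure D4:**
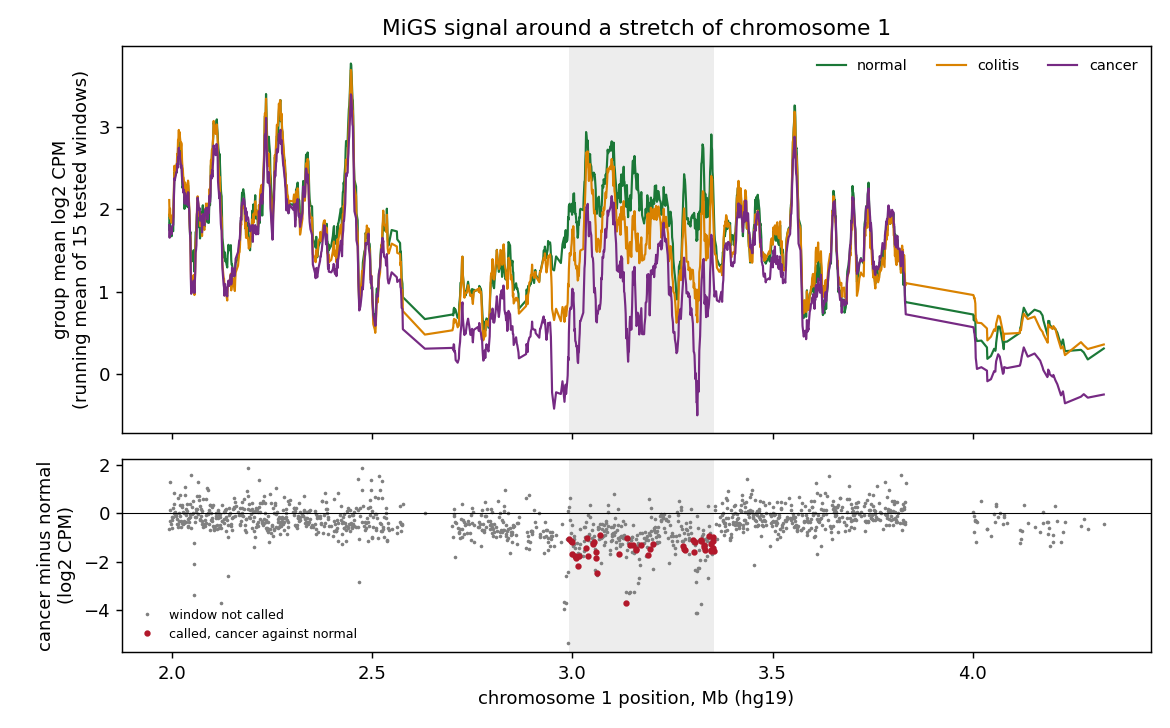
MiGS signal along chromosome 1 (hg19) around the stretch from 2992001 to 3354000 (grey). Above, group means of log2 CPM as a running mean of 15 tested windows; below, cancer minus normal for each tested window, with called windows in red, whose median over the stretch is -1.05 against -0.26 in the flanks.

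In RNA of colitis against normal cultures, 6 lists passed camera with the preset correlation and no single gene passed in edgeR. None of the 6 passed with an estimated correlation (adjusted p between 0.105 and 0.346). WNT, R-spondin and BMP niche genes were higher in 28 of 45 cases (median log2 fold change 0.35, mean 0.79), with the BMP antagonist CHRDL2 44.3-fold and the secreted WNT modulator SFRP4 152-fold higher, and SFRP2 at 6 to 228 counts per colitis library and 0 to 3 per normal library. Glycolysis and hypoxia genes were lower in 30 of 34 cases (median -0.54), with the glucose transporter SLC2A1 4.74-fold and the lactate transporter SLC16A3 2.78-fold lower and EGLN3 9.48-fold higher. Inflammatory genes were higher in 22 of 36 cases (median 0.61), led by C3 at 45.1-fold and the alarmin IL33 at 68.4-fold. Regional transcription factors were higher in 37 of 61 cases (median 0.13), with NKX3-2 14.3-fold, MEIS1 2.08-fold and PBX3 3.26-fold higher. The glycolysis mean of colitis replicate 2 (7.32 log2 CPM) lay above that of normal replicate 1 (6.63). The inflammatory mean of colitis replicate 4 (2.06) lay below that of normal replicate 1 (2.19). Means of the WNT and regional lists did not overlap between the groups.

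Camera gave adjusted p of 0.000133 for the WNT list, 3.42e-06 for glycolysis, 0.00022 for inflammatory genes and 0.00263 for regional factors. With an estimated correlation these were adjusted p = 0.105, 0.322, 0.34 and 0.105, and none passed. Smooth muscle and pericyte markers were higher (17 of 23, median 0.85, mean 1.05, adjusted p = 0.00301, and adjusted p = 0.346 with an estimated correlation), with MYH11 40.5-fold and ABCC9 10.2-fold higher, as were glial and neuronal markers (7 of 10, adjusted p = 0.0321, and adjusted p = 0.213 with an estimated correlation), led by STMN2 at 118-fold. The smooth muscle mean of colitis replicate 5 (3.77 log2 CPM) lay below those of normal replicates 2 (4.57) and 3 (5.30). The smooth muscle call was lost without colitis replicate 4 (adjusted p = 0.228) or normal replicate 1 (0.315). The glial call was lost without colitis replicate 4 (0.0565) or 5 (0.0631) or normal replicate 1 (0.184) or 3 (0.124), with X genes added (0.145), without a filter (0.206) and with only the groups compared (0.0526). The other 16 lists did not pass, among them cell cycle (median 0.17, adjusted p = 0.31, although camera ranked the list down) and interferon response (0.11, 0.402), and 1 myofibroblast gene passed as lower when adjusted over the list alone.

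Several of these 16 lists passed camera when 1 library was left out. Cell-cycle genes passed as lower in colitis cultures without colitis replicate 5 (adjusted p = 1.35e-08) or normal replicate 3 (0.000615). HOX genes (median -0.05, mean 0.44, adjusted p = 0.0789) passed as higher without colitis replicate 2 (0.0253), colitis replicate 5 (0.0178) or normal replicate 3 (0.0213), without a filter (0.0273) and with a stricter one (0.0248). Collagen and matrix genes (median -0.49, adjusted p = 0.0789) passed as lower without colitis replicate 2 (0.0026) or normal replicate 2 (0.0164), and myofibroblast genes (median -0.29, adjusted p = 0.136) without colitis replicate 2 (0.0026) or normal replicate 1 (0.0173). Leukocyte markers passed as lower without colitis replicate 2 (0.0109) or normal replicate 1 (0.042), and TGF-beta targets as lower without colitis replicate 2 (0.0253). Without normal replicate 2 interferon genes passed as higher (0.0471) and DNA methylation and chromatin writers as lower (0.0366), and without normal replicate 3 endothelial markers as higher (0.0323). None of these lists passed with all libraries and an estimated correlation (adjusted p between 0.335 and 0.812).

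No single gene passed between colitis and normal cultures. edgeR called 0 genes (smallest adjusted p = 0.999), with 314 higher and 204 lower at unadjusted p below 0.05, which is 3.39% of genes, while DESeq2 called 82 higher and 20 lower. Values of 1075 genes (7.03%) did not overlap between the groups, against an average of 10% over random groupings. Among the genes nearest the threshold were RARRES1 (8.32-fold higher, log2 fold change 3.06, SE 0.53), ACKR4 (13.9-fold), the antisense gene MAP3K4-AS1 (7.47-fold) and GNA14 (22.9-fold). Since the strand setting of the counting is not given, MAP3K4-AS1 cannot be told from its sense partner. The RNA-binding protein gene IGF2BP3 was 11.8-fold, TSPAN14 2.36-fold and the receptor-like gene PTK7 2.49-fold lower. PKD1P2 and MTND1P23, pseudogenes with uncertain counts, were 12-fold and 53.8-fold lower. LRRC15, a myofibroblast gene, was 94.3-fold lower (log2 fold change -6.56, SE 1.53, adjusted p = 0.999).

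MiGS called 2 windows between colitis and normal cultures, both higher in colitis. On chromosome 19 from 49937001 to 49938000 signal was 5.59-fold higher (log2 fold change 2.48, SE 0.28, adjusted p = 0.0471; 2.30 ± 0.50 against -0.18 ± 0.56 log2 CPM, SD, n = 4 and 3), and in cancer cultures it was 2.45 ± 0.22 (SD, n = 4). On chromosome 4 from 7228001 to 7229000 it was 4.13-fold higher (log2 fold change 2.05, SE 0.24, adjusted p = 0.0471). At unadjusted p below 0.05 stood 17490 windows, which is 4.30%, while edgeR called 0 and DESeq2 65. No window was called without colitis replicate 1, 2 or 4, and 4 were called without colitis replicate 5. Without normal replicate 1 the count was 434 (412 higher), without normal replicate 2 it was 11, and without normal replicate 3 it was 10.

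On average, cell-cycle genes and immediate-early and stress genes were lower, and interferon-response and inflammatory genes higher, in cancer than in colitis cultures. The interferon mean of cancer replicate 4 (4.01 log2 CPM) lay below that of colitis replicate 4 (4.41). Its inflammatory mean (2.30) lay below those of colitis replicates 2 (2.53) and 5 (2.56). The cell-cycle and immediate-early means did not overlap between these groups. Of the 47 cell-cycle genes, 45 were lower in cancer (median log2 fold change -2.47), with UBE2C 11.4-fold, CENPA 8.28-fold and MYBL2 7.53-fold lower (camera adjusted p = 3.47e-17, and adjusted p = 0.553 with an estimated correlation). Mitochondrial genes held 11.1 ± 5.53% of counts (SD, n = 4) in cancer and 6.54 ± 2.25% (SD, n = 3) in colitis cultures (2-sided exact permutation p = 0.171, where the smallest possible p is 0.0571), and with that share as a covariate the cell-cycle median was -1.51 (adjusted p = 7.99e-11, and adjusted p = 0.589 with an estimated correlation). Of the 45 interferon-response genes, 44 were higher (median 1.67), with the antigen presentation genes TAP1 3.33-fold, HLA-E 2.64-fold and HLA-B 5.77-fold higher (adjusted p = 6.03e-14, and adjusted p = 0.553 with an estimated correlation). HLA genes share reads with close relatives, so their separate values are uncertain. Immediate-early genes were lower (29 of 38, median -0.44, adjusted p = 0.0176, and adjusted p = 0.553 with an estimated correlation), with MYC 2.43-fold and FOSL1 4.32-fold lower. That call was lost with the mitochondrial share (adjusted p = 0.0909) or the cell-cycle mean (0.329) as a covariate. Inflammatory genes were higher (25 of 36, median 0.99, adjusted p = 0.0378, and adjusted p = 0.72 with an estimated correlation), with CXCL14 1316-fold higher and SAA1 at 41 to 640 counts per cancer library and 0 to 2 per colitis library. The inflammatory call was lost without cancer replicate 2 (adjusted p = 0.481), cancer replicate 3 (0.181) or colitis replicate 4 (0.198), with a stricter filter (0.195) and with those covariates (0.128 and 0.0509). The other 18 lists did not pass, and 36 cell-cycle, 5 interferon and 3 inflammatory genes, 1 leukocyte marker (higher) and 1 mesothelial marker (lower) passed when adjusted over the list alone.

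Smooth muscle markers, TGF-beta targets and matrix-degrading proteases passed between cancer and colitis cultures under some settings. Smooth muscle and pericyte markers had a median log2 fold change of -1.03 (camera adjusted p = 0.251). They passed as lower in cancer with the mitochondrial share as a covariate (median -1.44, adjusted p = 0.0215, and adjusted p = 0.589 with an estimated correlation), with the cell-cycle mean as a covariate (-2.10, adjusted p = 2.14e-05, and adjusted p = 0.194 with an estimated correlation) and without colitis replicate 5 (0.000328). TGF-beta targets had a median of 0.58 (adjusted p = 0.0753). They passed as higher with the mitochondrial share as a covariate (0.52, adjusted p = 0.0222, and adjusted p = 0.589 with an estimated correlation), without a filter (0.0457) and without cancer replicate 3 (0.0318) or colitis replicate 2 (0.00739). Proteases and their inhibitors had a median of 0.55 (camera adjusted p = 0.179) and passed as higher with fry (adjusted p = 0.0446) and, in camera, without a filter (0.0342). With the main filter and an estimated correlation they did not pass camera (adjusted p = 0.553).

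No single gene passed between cancer and colitis cultures either. edgeR called 0 genes (smallest adjusted p = 0.191), with 1072 higher and 1332 lower at unadjusted p below 0.05, while DESeq2 called 408 higher and 433 lower. PTK7 was 3.21-fold higher in cancer (8.48 ± 0.10 against 6.73 ± 0.56 log2 CPM, SD, n = 4 and 3), SLC2A10 2.43-fold, the interferon-inducible factor ETV7 11.9-fold and the pseudogene PKD1P2, with uncertain counts, 16.4-fold higher. PAX8-AS1 was 14.1-fold lower (log2 fold change -3.82, SE 0.50, adjusted p = 0.191), the nucleolar gene FBL 3.16-fold, the ribosomal protein gene RPL9 3.02-fold, ITGB3BP 3.42-fold and C19orf48P 3.15-fold lower. Values of 2837 genes (18.6%) did not overlap between these groups, against an average of 5.71% over random groupings. The share of any 1 grouping can lie far from that average, since genes vary together.

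MiGS called 5 windows between cancer and colitis cultures, all lower in cancer. On chromosome 11 the mean read equivalents per library were 0.4 in cancer and 44.2 in colitis cultures from 1891001 to 1892000 (log2 fold change -4.24, SE 0.45, adjusted p = 0.0101) and 2.9 against 61.9 from 1892001 to 1893000. On chromosome 2 from 114033001 to 114034000 it was 13.8-fold lower (-1.66 ± 0.72 against 2.13 ± 0.72 log2 CPM, SD, n = 4 and 4), and on chromosome 13 from 88329001 to 88330000 7.77-fold lower. On chromosome 19 from 36642001 to 36643000 read equivalents were 1.1 against 23.4. At unadjusted p below 0.05 stood 86469 windows, while edgeR called 0 and DESeq2 10868. The count was 9623 without cancer replicate 1, 0 without cancer replicate 2, 10 without cancer replicate 3 and 9 without cancer replicate 4. It was 9 without colitis replicate 1, 2 without colitis replicate 2 or 5, and 0 without colitis replicate 4.

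Fold changes of cancer and colitis cultures against the shared normal cultures were correlated across genes in RNA (Pearson's r = 0.526; genes are not independent replicates). Simulated unchanged groups against the same controls gave 0.537. The covariance was 0.501 against a simulated 0.313. In MiGS the correlation across windows was 0.531 against a simulated 0.572, and the covariance 0.121 against 0.0811. The 3 normal cultures could not be split into parts of at least 2 libraries each, so part of any excess may come from the shared controls.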

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

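The weighing of the 2 patterns in this part rests on tests chosen after the result was seen, except those of transcript length for cell-cycle genes and of the relation to cell-cycle expression.

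Of 256 groups of 4 cultures tested for a single distant value with Dixon's test, 15 had one (5.86%), and chance gives about 1 in 20. All 15 were in cancer cultures, and groups of 3 were not tested. In RNA only the cancer group held 4 cultures, so a distant gene value could be found in no other group. Single cultures stood above the others in log2 CPM for CD14 (8.96 in cancer replicate 2, next 5.83), DUSP2 (0.327 in cancer replicate 4, next -3.05), FRZB (4.013 in cancer replicate 1, next 1.645), HBEGF (2.854 in cancer replicate 4, next 1.451), KCNMB1 (-2.322 in cancer replicate 1, next -4.07), PTK7 (8.621 in cancer replicate 3, next 8.45), SLC39A8 (6.293 in cancer replicate 2, next 5.366) and SPARC (12.738 in cancer replicate 4, next 11.76). Single cultures stood below the others for COL11A1 (-0.235 in cancer replicate 2, next 8.592), EDN1 (2.359 in cancer replicate 4, next 5.772), HELLS (1.021 in cancer replicate 3, next 2.707), PRG4 (-4.069 in cancer replicate 2, next -2.54), SLC16A3 (7.689 in cancer replicate 1, next 8.586) and XAF1 (5.454 in cancer replicate 4, next 6.97). In MiGS the window on chromosome 19 from 49936001 was lowest in cancer replicate 2 (2.646, next 3.026). No explanation was tested for these values.

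Mitochondrial genes, which the comparisons leave out, held a mean of 11.12% of RNA counts in cancer and 6.07% in normal cultures.

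Cell-cycle genes were lower (median log2 fold change -2.24, as in 46 of 47 genes) and interferon genes higher in cancer than in normal cultures. Gene length, related to fold change (median -0.58 in the shortest 10% of genes, 0.24 in the longest), does not account for the cell-cycle list, since 10000 random sets matched on length and expression had medians around -0.04 (95% between -0.23 and 0.14). With the mitochondrial share as a covariate the cancer minus normal difference of the cell-cycle mean was -1.16 (SE 0.63, 95% interval -2.69 to 0.38; -2.14, SE 0.75, without it), and camera passed with the preset correlation (adjusted p = 1.43e-11) but not with an estimated correlation (adjusted p = 0.648). With the cell-cycle mean as a covariate the difference of the interferon mean was 2.17 (SE 1.10, 95% interval -0.52 to 4.86), against 2.27 (SE 0.70) without it. Camera gave adjusted p = 2.01e-07 and, with an estimated correlation, adjusted p = 0.509. Without 1 library this interferon difference ran from 1.10 to 3.41, with an interval that left out 0 in 1 of 10 fits. The cell-cycle difference with its covariate ran from -1.58 to -0.94 (2 of 10 fits). Both explanations stay open. A difference between the patients' disease states, passage or growth conditions of the cultures stays open and was not tested.

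The windows strongest over all libraries held 17.6% of reads in cancer cultures against 23.8% in normal cultures. A flatter enrichment was not told from a different set of strong windows. Depth stays open, since cancer libraries held 20.3 M reads on average against 16.8 M in normal cultures, and with reads as a covariate the difference in the share was -5.66 percentage points (SE 2.37, 95% interval -11.3 to -0.0651; -6.26, SE 2.08, without it) and stayed between -7.66 and -4.97 without 1 library, with an interval that left out 0 in only 3 of 11 such fits (cancer replicate 1, colitis replicate 5 or normal replicate 2), which is no support for depth but does not exclude it. Reads and share had a Pearson's r of -0.457 over 11 libraries (permutation p = 0.158, adjusted p = 0.317; Spearman's rho = -0.391, p = 0.238) and r = -0.296 without the 2 farthest, and within the 7 libraries not from cancer patients r was -0.140 (exact permutation p = 0.753, adjusted p = 0.753; rho = -0.179, p = 0.713) and 0.146 without the 2 farthest. A relation of this share to cell-cycle expression over 10 cultures (Pearson's r = 0.836, permutation p = 0.00315, adjusted p = 0.0126 over 4 relations; Spearman's rho = 0.806, p = 0.00721) fell to r = 0.571 without the 2 farthest cultures. Within the 6 cultures not from cancer patients r was 0.506 (exact permutation p = 0.279) and rho 0.257 (p = 0.658), and r was -0.481 without the 2 farthest, which cannot be told apart from no relation, since a missed p with 6 cultures excludes nothing and the prediction that it would was wrong; the efficiency of the pull-down could also differ and was not tested, since no input was used here.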

How the results depend on the processing

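Covariates and quantile normalization were tests chosen after the result was seen. So was edgeR on rounded read equivalents, the run nearest to the planned edgeR test on window counts. Limma took the place of that planned test, since the files hold signal. The other alternatives were planned. No called list or named window changed direction while called. Smooth muscle markers, not called in cancer against normal cultures, turned and passed as lower with the cell-cycle covariate (adjusted p = 0.016), and the balance of MiGS calls in cancer against normal cultures turned from 135 higher and 374 lower to 2150 and 1485 without normal replicate 1. Of 282 alternative values of 16 called lists, 220 stayed past the threshold in the same direction and 62 lost the call. Of 881 values of 50 lists that were not called, 766 kept their side and direction, 34 passed in the same direction, 80 turned without passing and 1 turned and passed. Of 105 alternative counts, 48 stayed within 1.5 times. Of 5073 values of named genes 145 passed the threshold and 61 changed direction without passing it, and of 294 values of named windows 95 lost the call. The cause was not tested except where the construction shows it. Promoter alternatives, the CpG offset, CpG-dense windows and repeated reads were not run.

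RNA gene counts for cancer against normal, colitis against normal and cancer against colitis cultures were 973, 102 and 841 with DESeq2. In cancer against normal cultures 2 genes were called without a filter and 1 with the cell-cycle mean as a covariate. Leaving out 1 library gave 0 to 486, 0 to 0 and 0 to 0 genes.

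MiGS window counts for the same comparisons, against 509, 2 and 5, were 443, 1 and 4 with total-read scaling, 501, 2 and 8 with RLE factors, 797, 0 and 30 with a filter of 5, 227, 1 and 2 with a filter of 20, 67, 0 and 121 with only the groups compared, 271, 3 and 26 with 500 bp windows, 216, 0 and 35 with quantile normalization, 3, 0 and 0 with the top share as a covariate, 449, 0 and 0 with edgeR, and 12662, 65 and 10868 with DESeq2. Leaving out 1 library gave 84 to 28045, 0 to 434 and 0 to 9623 windows.

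The replicate numbers do not pair the samples, as correlations of same-numbered cultures ran from -0.13 to 0.166 in RNA and from -0.18 to 0.114 in MiGS. With the replicate block 1 gene was called in colitis against normal cultures, PLA2G2A, and 167, 0 and 7 windows. The block gave adjusted p = 0.26 for immediate-early genes in cancer against colitis cultures and, in colitis against normal cultures, 0.64 for glial markers and 0.159 for regional factors, and it ended no other list's call. In colitis against normal cultures it made cell-cycle genes pass as lower (5.44e-20) and HOX genes as higher (0.0246), and in cancer against colitis cultures HOX genes (0.0395) and smooth muscle markers (0.000115) as lower and proteases as higher (0.0379). Under it the direction turned without passing for collagens (0.951), immediate-early genes (0.0528), epithelial markers (0.775) and TGF-beta targets (0.754) in colitis against normal cultures, and for collagens (0.344), glycolysis (0.995) and myofibroblast genes (0.891) in cancer against colitis cultures.

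With an estimated correlation adjusted p was 0.599 for cell cycle, interferon, inflammatory and WNT lists and 0.66 for glycolysis and immediate-early genes in cancer against normal cultures. In colitis against normal cultures it was 0.105 for WNT and regional factors, 0.322 for glycolysis, 0.34 for inflammatory genes, 0.346 for smooth muscle and 0.213 for glial markers. In cancer against colitis cultures it was 0.553 for cell cycle, interferon and immediate-early genes and 0.72 for inflammatory genes. With fry, in the order of the first comparison, it was 0.0969, 0.0818, 0.067, 0.0626, 0.203 and 0.298. In the second it was 0.0791, 0.0686, 0.331, 0.363, 0.433 and 0.0686, and in the last 0.172, 0.172, 0.208 and 0.388.

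Immediate-early genes in cancer against normal cultures lost the call with the stricter filter (0.0508), upper-quartile factors (0.0516), the mitochondrial covariate (0.195) and the cell-cycle covariate (0.388), and in cancer against colitis cultures with the covariates (0.0909 and 0.329). Inflammatory genes in cancer against colitis cultures lost it with the stricter filter (0.195) and the covariates (0.128 and 0.0509). Glial markers lost it with X genes added (0.145), no filter (0.206) and only the groups compared (0.0526). The cell-cycle covariate removes its own list (0.84 and 0.952) by construction.

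Leaving out 1 library, adjusted p in cancer against normal cultures ran from 4.93e-26 to 5.84e-08 for cell cycle, 3.40e-17 to 1.30e-08 for interferon, 1.26e-08 to 0.000955 for inflammatory, 0.000431 to 0.0333 for glycolysis, 0.00184 to 0.0333 for WNT and 0.00586 to 0.193 for immediate-early genes. In colitis against normal cultures it ran from 1.40e-10 to 0.01001 for glycolysis, 6.28e-05 to 0.0323 for WNT, 4.53e-05 to 0.031 for inflammatory genes, 0.00184 to 0.0184 for regional factors, 2.62e-07 to 0.315 for smooth muscle and 0.01001 to 0.184 for glial markers. In cancer against colitis cultures it ran from 2.28e-20 to 6.59e-12 for cell cycle, 1.06e-17 to 1.27e-09 for interferon, 0.00301 to 0.0427 for immediate-early and 0.00301 to 0.481 for inflammatory genes.

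Lists not called passed in colitis against normal cultures for HOX genes without a filter (0.0273) and with the stricter one (0.0248). Between cancer and colitis cultures proteases passed without a filter (0.0342) and with fry (0.0446), TGF-beta targets without a filter (0.0457) and with the mitochondrial covariate (0.0222), and smooth muscle markers with the mitochondrial (0.0215) and cell-cycle covariates (2.14e-05). In cancer against normal cultures the cell-cycle covariate gave 0.0418 for collagens and 0.0378 for myofibroblast genes.

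The direction of other lists turned without passing in these cases. In cancer against normal cultures these were epithelial and leukocyte markers without a filter (0.961 each), promoter methylation and glial markers with the stricter filter (0.805 each), glial markers with upper-quartile factors (0.931), only the groups compared (0.819) and fry (0.906), HOX genes (0.632) and smooth muscle markers (0.602) with the mitochondrial covariate, and p53 genes (0.749) and HOX genes (0.332) with the cell-cycle covariate. In colitis against normal cultures these were mesothelial markers without a filter (0.753), endothelial markers with the stricter filter (0.702), epithelial markers with only the groups compared (0.908) and p53 genes and epithelial markers with fry (0.952 each). In cancer against colitis cultures these were endothelial (0.832) and epithelial markers (0.804) without a filter, epithelial markers with upper-quartile factors (0.954), promoter methylation markers with the mitochondrial covariate (0.994) and, with the cell-cycle covariate, p53 genes (0.802), collagens and myofibroblast genes (0.332 each), chromatin writers (0.952) and endothelial markers (0.898).

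Leaving out 1 library changed the side or direction of lists not called as follows. Adjusted p in cancer against normal cultures ran from 0.0353 to 0.859 for chromatin writers, 0.488 to 0.953 for HOX, 0.157 to 0.912 for p53, 0.0677 to 0.864 for endothelial, 0.666 to 0.994 for epithelial, 0.666 to 0.979 for glial, 0.417 to 0.929 for leukocyte, 0.36 to 0.967 for smooth muscle and 0.311 to 0.883 for myofibroblast genes. In colitis against normal cultures it ran from 1.35e-08 to 0.558 for cell cycle, 0.0178 to 0.315 for HOX, 0.0026 to 0.938 for collagens and for myofibroblast genes, 0.0253 to 0.938 for TGF-beta, 0.0366 to 0.752 for chromatin writers, 0.182 to 0.991 for p53, 0.173 to 0.938 for immediate-early, 0.0471 to 0.274 for interferon, 0.0323 to 0.931 for endothelial, 0.199 to 0.934 for epithelial, 0.0109 to 0.405 for leukocyte and 0.0565 to 0.897 for mesothelial genes. In cancer against colitis cultures it ran from 0.48 to 0.968 for chromatin writers, 0.00739 to 0.209 for TGF-beta, 0.227 to 0.849 for collagens, 0.351 to 0.924 for glycolysis, 0.718 to 0.924 for endothelial, 0.498 to 0.96 for epithelial, 0.000328 to 0.713 for smooth muscle and 0.144 to 0.895 for myofibroblast genes.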

Other observations

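The tests of gene families, of the chromosome 1 stretch and of other splits were chosen after the result was seen, except the splits for glycolysis and WNT lists and the comparison of distances.

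Ribosomal protein genes were lower in cancer cultures. All 79 ribosomal protein genes were lower than in normal cultures (median log2 fold change -1.22; 78 with total-count scaling) and than in colitis cultures (-1.28), with means of 7.50 ± 0.42 log2 CPM (SD, n = 4) in cancer, 8.82 ± 0.13 (SD, n = 3) in colitis and 8.67 ± 0.63 (SD, n = 3) in normal cultures. Among 6 families picked from the genes with small p, camera called them against normal cultures (adjusted p = 8.77e-33, and adjusted p = 0.17 with an estimated correlation) and against colitis cultures (adjusted p = 1.87e-39, and adjusted p = 0.19 with an estimated correlation). Colitis did not pass against normal cultures (52 of 79 higher, median 0.05, adjusted p = 0.0611).

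Cytosolic aminoacyl-tRNA synthetases and proteasome subunits were lower than in normal cultures in both patient groups. In cancer cultures 16 of 18 and 31 of 35 were lower (median -0.50 in both, adjusted p = 3.15e-05 and 1.84e-06, and adjusted p = 0.17 and 0.267 with an estimated correlation). In colitis cultures 16 of 18 and 33 of 35 were lower (medians -0.21 and -0.16, adjusted p = 0.00194 in both, and adjusted p = 0.481 and 0.532 with an estimated correlation). In cancer against colitis cultures 17 of 18 and 30 of 35 were lower (medians -0.34 and -0.37, adjusted p = 0.0101 and 0.00235, and adjusted p = 0.3002 and 0.363 with an estimated correlation). Since families were picked from these data, the p-values are no independent evidence. Both comparisons with normal cultures share controls, and simulated unchanged groups gave correlated fold changes across genes (Pearson's r = 0.537, observed 0.526). A decrease in both groups is therefore no independent evidence either. Sets matched on length and expression were not drawn for these families. Those for ribosomal protein genes had medians around -0.21 in colitis and -0.30 in cancer against normal cultures. Whether the colitis medians differ from such sets was not tested.

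HLA class I and II genes, which present antigen, were higher in cancer than in colitis cultures (10 of 11, median 1.73, adjusted p = 5.11e-07, and adjusted p = 0.19 with an estimated correlation) and than in normal cultures (9 of 11, median 1.02, adjusted p = 0.00666, and adjusted p = 0.274 with an estimated correlation), and lower in colitis than in normal cultures (10 of 11, median -0.95, adjusted p = 0.000217, and adjusted p = 0.481 with an estimated correlation). The 5 apolipoprotein L genes were all higher in cancer than in normal cultures (median 1.32, adjusted p = 0.000943, and adjusted p = 0.17 with an estimated correlation), as were 4 of 5 against colitis cultures (median 1.54, adjusted p = 0.0109, and adjusted p = 0.262 with an estimated correlation), while colitis did not pass against normal cultures (3 of 5, median 0.91, adjusted p = 0.0611). Replication-dependent histone genes were higher in cancer than in colitis cultures (9 of 12, median 0.79, adjusted p = 0.00931, and adjusted p = 0.262 with an estimated correlation). They did not pass in cancer against normal cultures (9 of 12 higher, median 0.38, adjusted p = 0.0791) or in colitis against normal cultures (8 of 12 lower, median -0.15, adjusted p = 0.179).

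Transcript length may not be the whole cause of the ribosomal change, since matched random sets had medians around -0.30 (95% between -0.46 and -0.07) against -1.22.

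On chromosome 1, the stretch from 2992001 to 3354000 held 48 called lower windows within 400000 bp, as many as in only 1 of 35 splits of the cultures, the real one, which argues weakly against chance (without adjustment; the highest other split, cancer replicate 3 with the normal cultures, held 37 from 2983001 on the same chromosome, and the median was 11). Whether the lower share of reads in the top windows in cancer cultures is the whole cause stays open. The share was 14.2 to 20.1% in cancer and 20.6 to 27.3% in the other cultures, without overlap, so adjustment rests on differences within groups. The stretch was also chosen for its low signal in cancer cultures, which the interval below does not allow for. With that share as a covariate the cancer minus normal difference of the stretch mean was -1.05 (SE 0.28, 95% interval -1.71 to -0.38). The interval stayed below 0 without any 1 of the 11 libraries. The covariate ended all 48 calls in the stretch and left 3 called windows in the genome, with a median log2 fold change of -1.05 before and after and a median SE that rose from 0.30 to 0.43. Relative to windows of the same strength, the median of the stretch with the covariate was -1.05. The lowest of 3974 other stretches of 362 kb had a median of -0.55. Since the stretch was chosen for its called lower windows in the same comparison, its rank as lowest does not correct for that choice. Fewer DNA copies of the stretch could shift all its windows alike, and the shift against the flanks (-0.97 at the 10th and -0.71 at the 90th percentile, a ratio of 0.74) does not decide between fewer copies and lower methylation.

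PRDM16, a gene of chromosome 1 chosen after its values were seen, had a log2 fold change of -5.41 (SE 1.38, edgeR adjusted p = 0.188) in cancer against normal cultures, and its position in the build of the windows was not used here.

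Cultures alike in RNA were compared with cultures alike in MiGS through 45 pairs of 10 cultures. Over all cultures Pearson's r of the distances was 0.471 (permutation p = 0.00979) and rho 0.369 (p = 0.0255), with r 0.332 without normal replicates 2 and 3. For deviations from the group means r was 0.619 with a permutation p of 0.449, and permuted cultures gave a median r of 0.61. Centring on groups alone gives such an r, so the prediction that a missed p would count against a relation was wrong, and whether one exists within groups cannot be told apart from none.

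Other splits of the cultures do not let chance be excluded for the counts and lists given here with a value above 0. edgeR called 0 genes in cancer against normal cultures (highest other split 3) and 0 in cancer against colitis cultures (highest other split 2). Each of the 35 splits gives at least 0 by definition, so these counts tell nothing about chance. For genes at unadjusted p below 0.05, 3 of 35 splits gave as many as the 2744 of cancer against normal cultures (highest 2947), and 2 of 35 as many as the 2404 of cancer against colitis cultures (highest 2634). The negative log10 of the camera p of the cell-cycle list was 18.76 in cancer against normal cultures (2 of 35 splits as large, highest other 22.71) and 17.8 against colitis cultures (4 of 35, highest 20.44). For interferon response it was 13.9 (5 of 35, highest 21.88) and 14.26 (5 of 35, highest 26.59). Chance is not excluded for the values above 0.

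For MiGS, 3 of 35 splits of cancer and normal cultures called as many as 509 windows, so chance is not excluded, and the highest other split, cancer replicate 1 with the 3 normal cultures against the other cancer cultures, called 6078. Another, which exchanged cancer replicate 1 and normal replicate 2, called 999. Both splits keep most cultures in their own group. Their counts therefore do not tell another structure of the samples from single cultures unlike the rest of their group, and neither was tested. In colitis against normal cultures 13 of 35 splits called as many as 2 windows (highest 44). In cancer against colitis cultures only the real split, 1 of 35, called 5 windows (highest other 2), a share under 0.05 without adjustment for the other split tests. That count was 0 without cancer replicate 2, without colitis replicate 4, with edgeR and with the top share as a covariate, and 9623 without cancer replicate 1, so it is weak evidence against chance.

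Between colitis and normal RNA libraries 10 splits are too few for a share under 0.05. The real and highest other values were 6.81 and 10.68 for the negative log10 p of glycolysis (2 splits as large) and 4.92 and 3.16 for that of WNT signals (1 split). For called genes they were 0 and 1, where all 10 splits reach 0 by definition.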
